A study of Mus musculus with 2 samples.

How the data were processed

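Output libraries of a STARR-seq experiment in activated mouse Th1 cells were made from 2 biological replicates, each from 30 ug of nucleic acid, per the labels. The values used here came from 1 table of regions, which per the file headers was derived from the alignments of both libraries on mm10. The aligner, the region caller, the test and the normalization are not given in the sources used here. For each region the authors deposited a signed effect (a score whose log base, scaling and direction are not stated), a p-value and an adjusted p-value (q-value), and the region's width. In the deposited table the width equals the end minus the start plus 1, so that the start counts from 1, and coordinates are given as they stand there. The deposited p-values and q-values gave 114722 tested regions for 82.2% of the listed regions when q was multiplied by the rank of p and divided by p (within 0.5), so that about 13.1% of tested regions were listed. The untested and unlisted regions, the input library and signal tracks of each library were not used here. Because both libraries were combined, no comparison between replicates was made, and the depth of each library is unknown. With no depth, the precision of a region's effect is known only through the authors' p-value. Wilson intervals on shares of regions cover counting error over regions only.

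Annotation was taken from GENCODE M21 and sequence from the GRCm38 assembly, which matches the mm10 coordinates of the deposited table. For each region, GC share, CpG observed over expected, the soft-masked share, the distance from its centre to the nearest annotated transcription start and the nearest protein-coding start within 100 kb were computed with Python 3.11.15, pysam 0.24.0 and samtools 1.23.1. A promoter region had its centre within 1000 bp of a start of any annotated gene, and other regions were called distal. To count copies, the 300 bp around the centre of each region, which for regions narrower than that include flanking sequence, were aligned to chromosomes 1 to 19, X, Y and the mitochondrial genome with minimap2 2.31 (k = 19, w = 10, N = 50, p = 0.5). A copy was a match with at least 95% identity over at least 240 bp, and a region with at least 2 was called multi-copy. Of windows 10 kb upstream of the regions, 6.20% were multi-copy. The 21 regions on other scaffolds were left out of all comparisons.

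Shares were compared with two-sided Fisher's exact tests, and means and correlations with two-sided permutation tests of 100000 resamples (20000 for alternatives) in numpy 2.4.6 and scipy 1.17.1. For 34 consensus sequences fixed before the data were examined, the presence of the consensus on either strand was tested in a logistic model of direction (positive or negative) with GC share, CpG observed over expected and width as covariates, in statsmodels 0.14.6. No model could be fitted for p53, which had no negative region, or HNF1, which was found in no region, so 32 were tested. Because the relation with GC was curved, a model with GC in categories of 5 percentage points was added after the data were seen, with under 40% and 75% or more as 1 category each. For 16 gene lists, a gene's value was the mean effect of its regions, and list genes were compared with all other genes with a region. The Benjamini-Hochberg method was used over consensus sequences and over lists, with a threshold of 0.05.

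The statistics were tested on simulated data. Directions were simulated on the 14973 regions with a curved relation to GC and odds ratios of 1.5 either way for 60 planted consensus effects. The curve was the same in promoter and distal regions. Consensus sequences found in few regions, among them ROR and NRF1, were not simulated. The linear model called 98.3% of these in the right direction and 25.3% of 150 without an effect, and the model with GC categories called 100% and 3.33%. Among 1000 simulated lists of 25 genes, 74.2% were called at an unadjusted p under 0.05 with a shift of 0.5 and 4.0% with no shift. The calls over 16 lists use an adjusted p and many lists have fewer genes with a region, so these shares do not give their power.

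Genes and regions named in the report were fixed by a rule: the 10 highest and 10 lowest effects, the 3 members of each list with the largest absolute mean effect, and every region given to Ifng, Tbx21, Stat4, Il12rb2, Il2ra, Gata3, Il4, Foxp3 and Bcl6. A further gene of that rule is not reported here. The rule also asked for an input level above the lower quartile, which could not be applied because no input level was used here. Some members that the rule named are given only through their list's values. Alternatives were a stricter adjusted p of 0.001, an absolute effect of at least 1, regions under 500 bp apart merged, promoter windows of 500 and 2000 bp, gene distances of 50 and 20 kb, the region of largest absolute effect, distal regions alone, the central 200 bp, Fisher's exact test for consensus sequences and a masked share over 80%. Added after the data were seen were GC categories, single-copy regions, promoter regions alone, an adjusted p of 0.001 for the other results and regions of 45 to under 65% GC. Figures were drawn with matplotlib 3.10.9 and tables handled with pandas 2.3.3.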

Results

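Regulatory activity of genomic fragments was measured by STARR-seq in activated mouse T helper 1 (Th1) cells, the CD4 T cells that make interferon gamma. In STARR-seq, fragments are placed in a reporter carried on an episome, and a fragment that acts as an enhancer raises its own transcription, so that its share in the RNA output is compared with its share in the DNA input. The primary cells came from C57BL/6NJ mice and were cultured for 4 days with interleukin-2 and interleukin-12 p70 (10 ng/mL each) and an antibody blocking interleukin-4 (2 ug/mL), and for 3 days with antibodies to CD3e (0.25 ug/mL) and CD28 (1 ug/mL), per the labels. The labels name these treatments for both libraries. The doses of the 2 interleukins were read for replicate 1 alone and those of the antibodies to interleukin-4 and CD28 for replicate 2 alone. There was 1 group, with 2 output libraries from biological replicates, for which the labels give the same donor identifier, and a stated size range of 200 to 400 bp. The values came from 1 table of regions made from both libraries together, so no value has a spread between replicates, and the read depth is unknown. Tests across regions or genes describe this table, in which regions are not independent replicates.

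The first question was which regions differed between output and input, and in which direction. The authors' deposited table listed 14994 regions, of which 14973 lay on chromosomes 1 to 19, X and Y (mm10 coordinates). Of these, 12083 had a positive effect and 2890 a negative effect, so that 80.7% were positive (95% Wilson interval 80.1 to 81.3%). The median effect was 0.80 among positive regions and -1.07 among negative regions in the authors' deposited table, and the extremes were 7.92 and -5.93. Regions had a median width of 625 bp. The scale and the direction of the effect are not given in the sources used here, and positive is read below as output above input. Only regions with an adjusted p under 0.01 were listed, and none had a positive effect below 0.37 or a negative effect above -0.43 in the authors' deposited table.

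**Figure D1:**
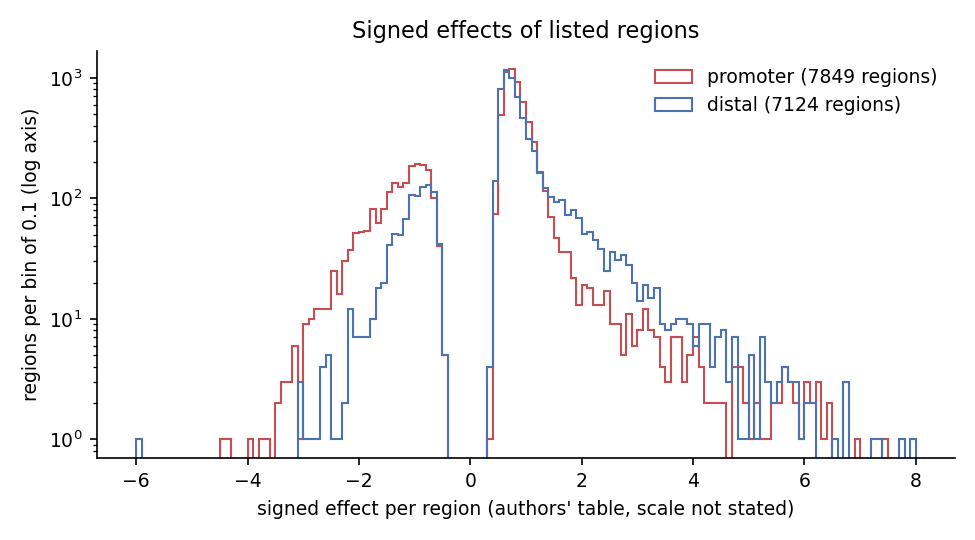
Number of regions (log axis) by signed effect in the authors' deposited table, in bins of 0.1, for 7849 promoter regions and 7124 distal regions. Promoter regions make up most of the negative side, and no region lies between -0.43 and 0.37.

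The listed regions given to regulators of the Th1 and other T helper programmes had positive effects. This is the sign of 80.7% of all regions, and no test was made against that share. Of 9 T helper genes chosen before the data were examined, 7 were the nearest protein-coding start, within 100 kb, of at least 1 region, and all 12 of these regions had positive effects. Tbx21, which encodes the Th1 master regulator T-bet, had 3 regions on chromosome 11. Their effects in the authors' deposited table were 1.01 at 97126801 to 97127400, 0.85 at 97083676 to 97084250, and 0.64 at 97115576 to 97115625, all intergenic, the last with its centre 269 bp from the gene's start. Ifng, which encodes interferon gamma, had 1 intergenic region, at 118418876 to 118419550 on chromosome 10, 21833 bp from its start, with an effect of 0.73 and an adjusted p of 0.00013 in the authors' deposited table. Stat4, which encodes the transcription factor activated by interleukin-12, had intronic regions on chromosome 1 with effects of 0.72 and 0.57 in the authors' deposited table. Genes of other T helper fates had regions of the same sign: the authors' deposited table gave effects of 0.91 and 0.79 in introns near Gata3, 0.71 in an intron near Il4 and 0.85 in an intron near Foxp3. For Bcl6, the regulator of follicular helper cells, the authors' deposited table gave 1.27 at the promoter (chromosome 16, 23988526 to 23989050) and 0.57 upstream. Il12rb2 and Il2ra were not the nearest protein-coding start of any listed region, and regions nearer to a neighbouring gene were not counted for them.

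The highest effects lay mostly in sequence with several copies in the genome. The region with the highest effect, 7.92 in the authors' deposited table, was intergenic on chromosome 3 (5860301 to 5860575), had no protein-coding start within 100 kb and had 5 copies. It was followed in the authors' deposited table by regions given to Zfp53 (7.76), Gvin1 (7.50), Gm10128 (7.35), Gm5861 (7.29), Vmn2r41 (6.94), Atg7 (6.76), Slc19a2 (6.76), Gm16434 (6.73) and Samd9l (6.51). Distances to these starts ranged from 62 bp for Gvin1 to 68729 bp for Vmn2r41, whose region lay 87 bp from the start of 2810047C21Rik1. Of the 10 regions, the one given to Zfp53 was single-copy, and 79.3% of it was soft-masked as repeats. The lowest effects lay mainly at GC-rich promoters. After an intergenic region on chromosome 10 (11491951 to 11492275, effect -5.93, no protein-coding start within 100 kb), the authors' deposited table gave -4.45 at Zdhhc18, -4.31 at Chn1, -3.90 at Vezf1, -3.78 at Cenpb, -3.60 at Phc1, -3.49 at Shf, -3.46 at Slc4a7, -3.37 at Nrf1 and -3.33 at Begain. Phc1 encodes a Polycomb protein and Cenpb a centromere protein. All 9 of these regions had centres within 734 bp of the gene's start, were single-copy and had GC contents from 64.9% at Phc1 to 77.8% at Zdhhc18.

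Multi-copy regions, for which the 300 bp around the centre matched at least 2 places in the genome, numbered 948 of 14973 (6.33%). For the 2862 regions narrower than 300 bp this window includes flanking sequence, so that the count is that of the site rather than of the region alone. They made up 61.1% of the 826 regions with an effect over 2, and 0.778% of the 11564 regions with an effect of 1 or less. Among regions of at least 300 bp, a restriction chosen after the data were seen, the shares were 58.9% of 433 and 0.693% of 9672. Of the multi-copy regions 936 had a positive effect. How reads were assigned among copies is not given in the sources used here, so the effects of genes in duplicated families are uncertain.

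**Figure D2:**
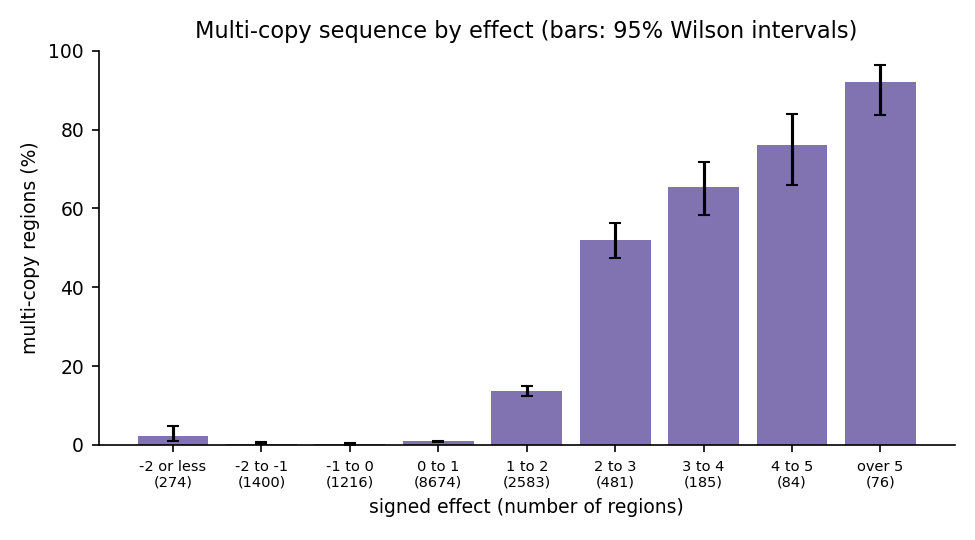
Share of multi-copy regions (%), judged on 300 bp around the centre, in classes of signed effect, with 95% Wilson intervals and the number of regions in each class under the axis. The share was 2.19% among regions at -2 or less and 92.1% among those over 5.

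Promoter regions were compared with distal regions to ask whether activity differed by location. Regions with a centre within 1000 bp of an annotated transcription start were positive in 5891 of 7849 cases (75.1%, 95% Wilson interval 74.1 to 76.0%), and distal regions in 6192 of 7124 (86.9%, 86.1 to 87.7%). The share was thus 11.9 percentage points lower at promoters (two-sided Fisher's exact test, odds ratio 0.453, 95% interval 0.416 to 0.493, p = 7.74e-77). Mean effects were 0.39 at promoters and 0.80 in distal regions (two-sided permutation test, p = 1e-05, the smallest that the permutations can give). The lowest share by distance, 64.8% of 1140 regions, was found over 250 to 500 bp from a start, and the highest, 90.6% of 1233 regions, over 2000 to 5000 bp. Among positive regions the medians were nearly equal, at 0.81 and 0.80, whereas negative promoter regions had a median of -1.16 and negative distal regions one of -0.95. The difference in share was no longer called once base composition was included (logistic models, n = 14973 regions): the odds ratio was 1.08 (0.959 to 1.21, p = 0.205) with GC share and width as linear terms, and 0.865 (0.731 to 1.02, p = 0.0902) with GC in categories, which was chosen after the data were seen.

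GC content was related to the direction of effect at both ends of its range. Over all regions, effect fell with GC share (Pearson's r = -0.319, Spearman's rho = -0.237, permutation p = 1e-05 and Benjamini-Hochberg adjusted p = 4e-05 for both, over 4 sets of regions). The relation was not a straight line. In distal regions 66.2% had a negative effect at under 35% GC, 2.16% at 50 to under 55% and 92.3% at 75% or more, the last in 13 regions. In promoters the shares were 3.24% at 50 to under 55% GC, 41.2% at 65 to under 70% and 94.1% at 75% or more. Negative distal regions had a median GC content of 42.7% and positive distal regions one of 51.0%, while negative promoter regions had 69.6% and positive promoter regions 60.6%. Within distal regions r was 0.0651 (permutation p = 5e-05, the smallest that the permutations can give, rho = 0.0434), the opposite sign to that in promoters (r = -0.530, rho = -0.445). These are correlations across regions of 1 table.

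**Figure D3:**
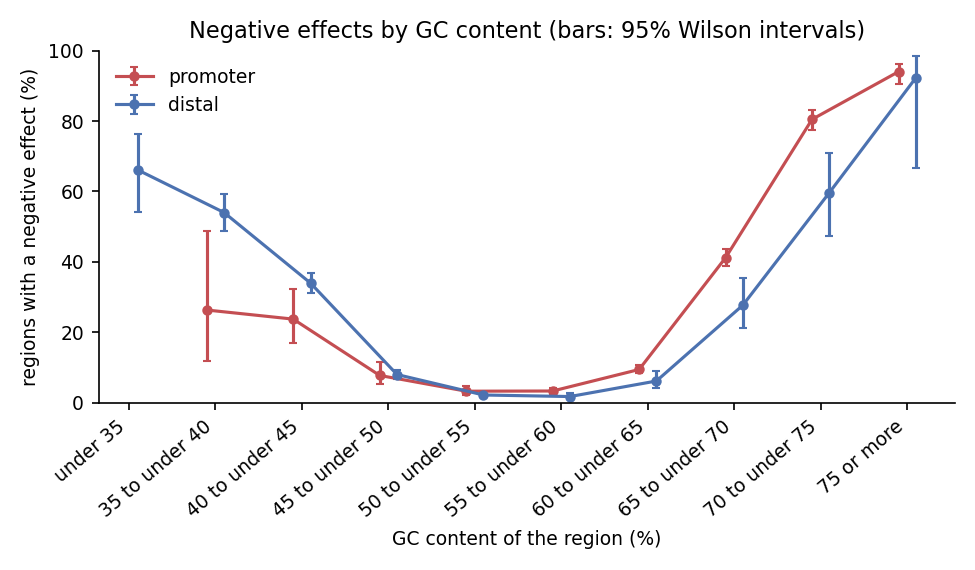
Share of regions with a negative effect (%) by GC content for promoter and distal regions, with 95% Wilson intervals (classes with under 10 regions are left out). The share was lowest from 50 to under 60% GC and rose towards both ends.

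Repeats were more often positive than other sequence. Of 875 regions with over 50% soft-masked sequence, 834 (95.3%) had a positive effect, against 11249 of 14098 others (79.8%; two-sided Fisher's exact test, odds ratio 5.15, p = 3.34e-38). The median effect of positive regions was 1.32 in repeats and 0.79 elsewhere. GC content and distance to a start, which also went with direction, were not included in this comparison. Whether repeats differ from other sequence of equal GC content and location was not tested. Among single-copy regions the odds ratio was 4.58 (Fisher's exact test, p = 1.3e-30), and 48.0% of the 321 single-copy regions with an effect over 2 were repeats, against 2.41% of the 11474 with an effect of 1 or less. Matches under 95% identity were not counted as copies, so single-copy repeats can still have diverged copies.

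Consensus sequences of transcription factors were searched to ask which of them went with positive effects. Listed positive regions were compared with listed negative regions, and sequences that were not listed were not searched. An odds ratio near or below 1 therefore does not show whether a consensus is enriched in listed regions over other sequence. Of 34 consensus sequences, 8 had a called odds ratio of a positive effect above 1 and 2 had one below 1, both with GC share as a linear term and with GC in categories. The positive group was led by CRE (TGACGTCA), the element of CREB and ATF factors, present in 3.96% of positive and 2.18% of negative regions (logistic model with GC categories, n = 14973 regions, odds ratio 2.20, 95% interval 1.61 to 3.01, Benjamini-Hochberg adjusted p = 9.53e-06), and by the promoter element NFY (16.6% and 9.72%, odds ratio 2.10, 1.78 to 2.47, adjusted p = 1.34e-17). CTCF had an odds ratio of 1.75, NRF1 of 1.69, YY1 of 1.43, ETS of 1.41, STAT of 1.37 and the CACGTG E-box of 1.23 in that model, with adjusted p from 2e-06 for ETS to 0.0332 for NRF1 and YY1. The 2 consensus sequences with odds ratios below 1 were ROR, present in 1.85% of positive and 2.42% of negative regions (n = 14973 regions, odds ratio 0.563, 0.406 to 0.781, adjusted p = 0.00461), and GATA, present in 6.51% and 6.16% (odds ratio 0.755, 0.617 to 0.925, adjusted p = 0.0245). In Fisher's exact test without covariates the odds ratio of GATA was 1.06 (adjusted p = 0.616). In that test ROR (0.757), YY1 (1.04), NRF1 (1.19) and the CACGTG E-box (1.11) were not called either. Among regions with an adjusted p under 0.001 in the authors' deposited table, the linear model no longer called STAT (odds ratio 1.26, adjusted p = 0.133), YY1 (1.35, adjusted p = 0.0804) or ROR (0.665, adjusted p = 0.163). In the central 200 bp it no longer called NRF1 (n = 14973 regions, 1.68, adjusted p = 0.123). With GC categories in distal or in promoter regions alone, CRE and NFY were called in both, STAT in distal regions, ETS in promoters and the others of these in neither. The odds ratio of CRE in distal regions, 4.82 (1.69 to 13.7), rests on 4 negative regions with the consensus.

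Among factors of the cytokine response, STAT and interferon elements had odds ratios above 1 in distal regions. With GC as a linear term these were 1.75 for STAT (n = 7124 regions, adjusted p = 0.000121) and 1.38 for IRF/ISRE (adjusted p = 0.0282). Over all regions the planned linear model gave IRF/ISRE an odds ratio of 0.955 (0.805 to 1.13), which was not called. With that linear term it also lay below 1 in the central 200 bp (0.932), at the stricter threshold of 0.001 (0.987) and in single-copy regions (0.935). Called values above 1 over all regions were 1.32 (1.09 to 1.61) with GC categories and 1.31 in Fisher's exact test without covariates. The STAT consensus was present in 12.8% of positive and 10.1% of negative distal regions, and the IRF/ISRE consensus in 8.58% and 10.5%, so that for IRF/ISRE the shares alone went the other way. With GC categories, the STAT consensus had an odds ratio of 1.86 in distal regions (n = 7124 regions, 1.44 to 2.41, adjusted p = 8.27e-05) and 1.01 in promoters (0.777 to 1.31), and the IRF/ISRE consensus, bound by interferon regulatory factors, had 1.57 in distal regions (1.21 to 2.05, adjusted p = 0.007) and 1.08 in promoters (0.806 to 1.44). The octamer OCT had an odds ratio of 2.11 in distal regions (n = 7124 regions, adjusted p = 0.02). The consensus of T-bet's family (T-box) had an odds ratio of 1.07 over all regions with GC categories (n = 14973 regions, 0.751 to 1.52, adjusted p = 0.886), RUNX of 1.03, NF-kB of 0.997 and NFAT of 0.946, none of them called in that model. Under other settings chosen before the data were examined, called odds ratios were 1.39 for RUNX in Fisher's exact test without covariates (adjusted p = 2.18e-08), and with a linear GC term 1.48 for NF-kB in distal regions (n = 7124 regions, adjusted p = 0.0208) and 0.618 for NFAT in the central 200 bp (adjusted p = 0.000299). AP-1, the consensus of Fos and Jun factors, was present in 18.3% of positive and 14.6% of negative regions (Fisher's exact test, odds ratio 1.31, adjusted p = 6.79e-06), with 10.5% and 6.18% in promoters and 25.7% and 32.3% in distal regions. With covariates its odds ratio over all regions lay below 1, at 0.745 (n = 14973 regions, 0.658 to 0.842, adjusted p = 1.07e-05) with GC as a linear term and 0.886 (0.768 to 1.02, adjusted p = 0.223) with GC categories, and in distal regions alone it was 0.914 with the linear term (adjusted p = 0.459). The planned model with a linear GC term called 14 positive and 3 negative consensus sequences, and the model with GC categories, added after the data were seen, called 10 and 2. On simulated directions with a curved GC relation the linear model called 25.3% of the consensus sequences given no effect, and the categories 3.33%. That simulation left out ROR and NRF1 and used the same GC curve in promoter and distal regions. Its shares are therefore not error rates of the calls reported here.

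**Figure D4:**
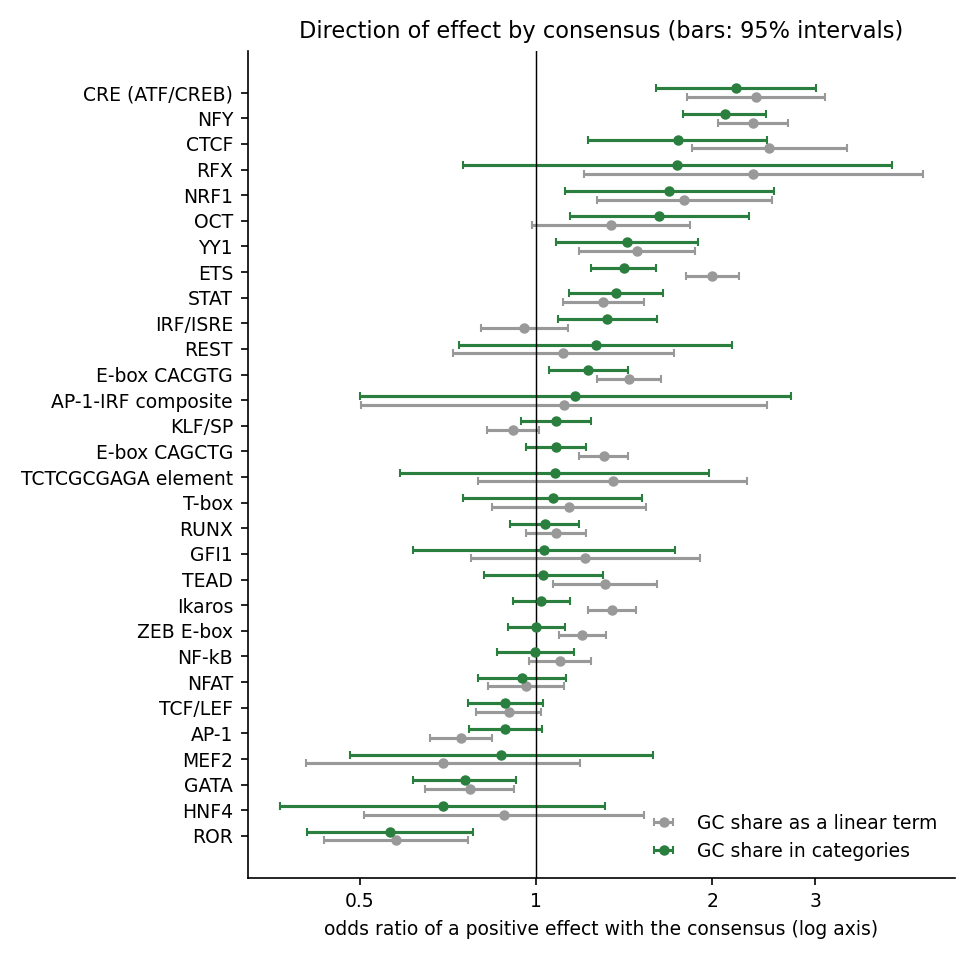
Odds ratio (log axis) of a positive effect for regions with each consensus sequence, with 95% intervals, from models with GC share as a linear term or in categories (those with very wide intervals are left out). NFY and CRE lie above 1 and ROR and GATA below 1 in both models, while Ikaros, TEAD and the ZEB E-box lie near 1 with GC categories.

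Gene lists were compared to ask whether regions near genes of a programme had higher effects than regions near other genes. A region was given to the nearest protein-coding start within 100 kb, and 9394 genes had at least 1 region. No list of the 16 passed the threshold for the mean effect (two-sided permutation tests, lowest adjusted p = 0.386). At an unadjusted permutation p under 0.05 there were the interferon and STAT response list, with a mean of 0.93 over 27 genes against 0.54 over other genes (p = 0.0416), and the cytosolic ribosomal proteins, with 0.83 over 45 genes (p = 0.0482). The difference from other genes, 0.387 for the interferon list and 0.289 for the ribosomal list, was 0.0531 and 0.111 in distal regions alone (permutation p = 0.826 and 0.665), and 0.163 and -0.0391 among regions of 45 to under 65% GC, chosen after the data were seen (permutation p = 0.244 and 0.712). All 27 interferon and STAT response genes with a region had a positive one, and 46 of the list's 48 regions were positive (Fisher's exact test over genes, adjusted p = 0.205). The list's highest gene means from the authors' deposited table were 1.90 for Ifit3, an interferon-induced gene whose regions had 2 copies, 1.58 for Isg15, an interferon-induced ubiquitin-like protein, and 1.38 for Cish, a STAT5 target that restrains cytokine signalling. All 45 ribosomal protein genes with a region had a positive one, more often than the 85.3% of all genes (Fisher's exact test, adjusted p = 0.0189), with means from the authors' deposited table of 1.95 for Rps20, whose region had 2 copies, 1.72 for Rpl17 and 1.39 for Rpl27. That call was lost among regions of 45 to under 65% GC (Fisher's exact test, adjusted p = 1), in distal regions alone (adjusted p = 0.817) and at an adjusted p under 0.001 in the authors' deposited table (adjusted p = 0.105). The interferon list was called in Fisher's exact test with the region of largest absolute effect per gene (adjusted p = 0.0258).

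Of the Th1 programme, 18 of 19 genes with a region had a positive one, and 37 of 40 regions were positive, with a list mean of 0.73 (permutation p = 0.409, adjusted p = 0.938). Its highest means in the authors' deposited table were 1.48 for Ccl5, a chemokine, 1.04 for Lta, the cytokine lymphotoxin alpha, and 1.03 for Gzmb, the cytotoxic protease granzyme B. The Th2 list had a positive region at 15 of 15 genes (mean 0.63, with 0.96 for Il13 and 0.82 for Il4ra in the authors' deposited table), Th17 at 8 of 10 (mean 0.48, with 1.73 for Il22, which had regions of up to 2 copies, and 1.22 for Stat3 in the authors' deposited table), Treg at 8 of 9 (mean 0.50) and Tfh at 8 of 9 (mean 0.76). In the Treg list Ikzf2, which encodes Helios, stood at -1.54 in the authors' deposited table, from 1 region 293 bp from its start with 69.7% GC. T cell receptor and activation genes had a positive region at 29 of 30 genes but a mean of 0.53, with 76 positive and 17 negative regions; their highest means in the authors' deposited table were 1.87 for Junb, a subunit of AP-1, 1.36 for Nfkb2 and 1.22 for Atf3. T cell identity genes had a positive region at 14 of 18 genes (mean 0.35, with 0.95 for Cd3d, 0.86 for Runx1 and 0.81 for Lef1 in the authors' deposited table). Glycolysis and mTOR genes had a mean of 0.66 over 18 genes and p53 targets one of 0.68 over 16 genes. Of the lists of other cell types, neuron markers had a mean of 0.74 over 8 genes, hepatocyte markers 0.64 over 3, skeletal muscle markers 0.47 over 3 and B cell markers 0.31 over 6. Myeloid markers had 0.93 over 7 genes, a value that rested on Fcgr3, with a mean of 4.18 in the authors' deposited table and regions of up to 3 copies, and that was 0.56 with single-copy regions alone.

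**Figure D5:**
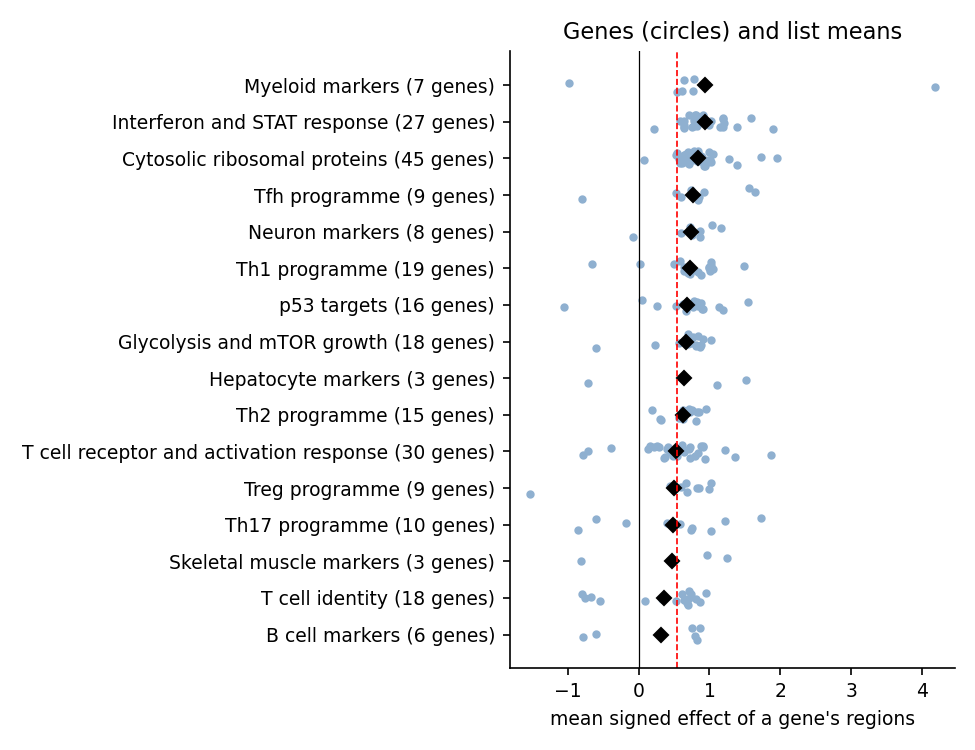
Mean signed effect of each gene's regions (circles) for 16 gene lists, from the authors' deposited table, with the list mean (diamonds) and the mean of other genes (dashed line). The lists overlap, and Fcgr3 among the myeloid markers stands apart at 4.18.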

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

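All tests of explanations given here were chosen after the results had been seen. The design has 1 group, so no biological explanation was tested for any of the patterns. Regions on unplaced or unlocalised scaffolds, outside every comparison of the report, numbered 21 in the authors' deposited table, of which 15 had a positive effect, with effects from -2.45 to 2.54.

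Negative effects were concentrated at both ends of GC content. Promoter position as the whole cause was argued against by the odds ratio of promoter against distal regions. It was 0.865 (0.731 to 1.02) with GC categories and width, above the 0.453 without covariates. GC categories and width were added together, so their parts in this move were not separated. CpG density as the whole cause of the low-GC end was argued against among regions with under 1 CpG per 100 bp, where 55.1% of 361 regions under 40% GC were negative, against 4.03% of 620 at 50 to under 60% GC, and it stays open for the high-GC end. The negative share at a GC end was at least 10.2 times that in the middle in both promoters and distal regions, where the lowest ratio rests on 7 negative regions of 21 promoter regions under 40% GC (33.3%, 95% Wilson interval 17.2 to 54.6%, against 3.28% in the middle). A recovery of fragments that differed with GC content between output and input, and a dependence of activity on base composition, would give the same values, and neither was tested.

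The largest positive effects lay in multi-copy sequence. Of the 274 regions with an effect under -2, 2.19% were multi-copy, against 61.1% of the 826 regions with an effect over 2. These shares cannot decide whether errors of either sign from reads assigned among copies were the cause. Only called regions were listed and no input level was used, so losses at multi-copy sites may have been harder to call than gains. Of the 505 multi-copy regions with an effect over 2, 2.97% lay near a small non-coding RNA gene of GENCODE M21 or matched the mitochondrial genome. This argued against RNA of those annotated genes or of mitochondrial inserts as the whole cause. Small RNA genes absent from that annotation, such as any transfer RNA genes it leaves out, could not be counted. For them the explanation stays open. Narrow regions as the cause were argued against because the multi-copy share over 2 was 111 times that at 1 or less among regions of at least 500 bp. A handling of repeated reads that differed between output and input, and activity of the repeated sequences themselves, were not tested and stay open.

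The AP-1 consensus, which goes with enhancers in activated T cells, had a called odds ratio below 1 with a linear GC term, although it was present in 18.3% of positive and 14.6% of negative regions (odds ratio 1.31 without covariates). A candidate explanation is the low GC content of negative distal regions: the odds ratio was 0.745 (0.658 to 0.842) with a linear GC term and 0.886 (0.768 to 1.02) with GC categories. The call ended because the estimate moved towards 1, with an interval of similar width. A smaller true difference within GC categories stays open.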

How the results depend on the processing

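Alternatives with GC categories, single-copy regions, promoter regions alone, 45 to under 65% GC, or an adjusted p under 0.001 for results other than the counts of regions were added after the data were seen. Leaving out a replicate and restricting regions by input depth were not run, since the authors' deposited table has 1 value per region for both libraries and no input level, and an adjusted p under 0.01 moved nothing because every listed region passes it. No paired analysis was possible because there is 1 group. Depth is unknown, and regions with small effects are absent from the list, so nothing can be said of sequences that were not listed. The numbers of positive and negative regions were 7279 and 1791 at an adjusted p under 0.001, and 3409 and 1674 at an absolute effect of at least 1, as fewer regions pass. The positive share was 67.1% at an absolute effect of at least 1, 81.6% with regions merged and 79.5% in single-copy regions. The difference in positive share between promoter and distal regions kept its direction and its call with windows of 500 and 2000 bp, merged regions, an adjusted p under 0.001 and single-copy regions, whereas the odds ratio was 1.08 with GC share and width and 0.865 with GC categories and width, neither called. The correlation of GC share and effect was 0.0651 in distal regions. The repeat result kept its direction and call in both alternatives. Called consensus sequences with an odds ratio above 1 numbered 14 in the planned model, 9 at an adjusted p under 0.001, 5 with GC categories in distal regions and 3 in promoter regions. Those with one below 1 numbered 3 in the planned model, 1 with Fisher's exact test, 5 in the central 200 bp, and 0 with GC categories in distal or in promoter regions alone. The cause of these changes was not tested, apart from the smaller sets of regions.

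Of 411 alternatives in all, 274 kept the direction and the side of the threshold or stayed within the spread. With the direction kept, 54 lost a call and 11 gained one (RUNX, NF-kB and NFAT in 1 each, KLF/SP in 3 and OCT in 5). Another 58 changed direction, whether or not the call changed, and 14 were counts or shares that moved by over 1.5 times or out of their interval. Among the 58, IRF/ISRE also gained a call in Fisher's exact test, in distal regions, and with GC categories over all and in distal regions. Others also lost a call, such as GATA in Fisher's exact test, TEAD with GC categories in distal regions and the promoter odds ratio with GC share and width. Most changes of direction were in values that were not called in the planned analysis. With Fisher's exact test without covariates the odds ratios on the other side of 1 were 1.31 for AP-1, 1.31 for IRF/ISRE, 0.975 for NF-kB, 1.16 for NFAT, 1.06 for GATA, 1.20 for TCF/LEF and 0.863 for the TCTCGCGAGA element. In distal regions alone they were 0.964 for the ETS-RUNX composite, 1.38 for IRF/ISRE, 0.940 for REST and 0.0233 for the TCTCGCGAGA element, which was found in 1 positive and 1 negative distal region. With GC categories they were 1.32 for IRF/ISRE, 0.997 for NF-kB and 1.08 for KLF/SP. With GC categories in distal regions they were 0.766 for the ETS-RUNX composite, 0.958 for RUNX, 1.57 for IRF/ISRE, 0.974 for GFI1, 0.781 for REST, 0.433 for the TCTCGCGAGA element, 0.892 for TEAD and 1.13 for MEF2, and in promoter regions 1.08 for IRF/ISRE, 0.903 for NF-kB, 1.10 for NFAT, 0.904 for the ZEB E-box and 1.10 for KLF/SP. At an adjusted p under 0.001 they were 0.648 for the ETS-RUNX composite, 0.992 for RUNX, 0.895 for GFI1 and 1.02 for KLF/SP, and in the central 200 bp 0.997 for T-box, 2.49 for HNF4 and 1.56 for MEF2. No gene list passed the threshold for the mean effect under any alternative run. The differences of list from other genes that changed sign were, in distal regions, -0.210 for Th1, -0.0797 for Th2, 0.0314 for Treg, -0.0530 for Tfh, -0.0403 for glycolysis and mTOR, -0.161 for p53 targets, -0.299 for neuron and -0.142 for hepatocyte markers. At 45 to under 65% GC they were -0.00463 for Th1, -0.0376 for Th2, -0.138 for glycolysis and mTOR, -0.0188 for neuron markers and -0.0391 for ribosomal proteins. Within 50 kb they were 0.0600 for Th17 and -0.333 for hepatocyte markers, and within 20 kb 0.140 for Th17 and 0.0468 for the T cell receptor list. In single-copy regions they were 0.0753 for Th17, 0.0429 for Treg, 0.0700 for the T cell receptor list and 0.00488 for skeletal muscle, and at an adjusted p under 0.001 0.0953 for the T cell receptor list. The cause of these changes was not tested.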

Other observations

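The comparisons in this part were chosen after the data were seen. Genes of some lists, both T cell programmes and lists not particular to T cells, were more often the nearest protein-coding start of a listed region of either sign than other genes were. Over all protein-coding genes 43.0% were given a region within 100 kb in this way, against 30 of 33 T cell receptor and activation genes (90.9%, Fisher's exact test, adjusted p = 3.11e-07 over 16 lists), 15 of 16 Th2 genes (93.8%, adjusted p = 0.000163), 27 of 33 interferon and STAT response genes (81.8%, adjusted p = 6.82e-05) and 19 of 28 Th1 genes (67.9%, adjusted p = 0.0267). By the same Fisher's exact test, the lists for glycolysis and mTOR (18 of 21, adjusted p = 0.000312), p53 targets (16 of 18, adjusted p = 0.000366), T cell identity (18 of 27, adjusted p = 0.0363) and ribosomal proteins (45 of 76, adjusted p = 0.0137) also passed. The Th17 (10 of 15, adjusted p = 0.0987), Treg (9 of 13, adjusted p = 0.11) and Tfh lists (9 of 12, adjusted p = 0.0669) did not pass in Fisher's exact test. In Fisher's exact test no difference was called for the lists of other cell types: hepatocyte markers had a region at 3 of 17 genes (17.6%, adjusted p = 0.0756), skeletal muscle markers at 3 of 16 (18.8%, adjusted p = 0.0987), myeloid markers at 7 of 19 and neuron markers at 8 of 16 (adjusted p = 0.693 for both), and B cell markers at 6 of 14 (42.9%, adjusted p = 1). These tests take genes as independent, whereas some list genes are neighbours, such as Il4 and Il13 of the Th2 list on chromosome 11. Under the nearest-start rule, being given a region also depends on the spacing of genes, which was not accounted for. The regions that were tested but not listed were not used here, and whether the shares follow from which sequences were in the library was not tested.

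Gene families at promoters were chosen after the values were seen and were redefined after their results were known, so that which of them passed depends on the definition and none is called here. Among 6950 single-copy regions within 1000 bp of a protein-coding start, 72.8 to 73.1% of other promoters were positive in each comparison. Replication-dependent histone genes were positive in 33 of 37 cases, with a median effect of 1.16 (Fisher's exact test, p = 0.0251). With families taken by symbol start, genes named Psma to Psmg were positive in 21 of 22 cases, Nduf genes in 21 of 22, Mrpl and Mrps genes in 24 of 26 and Polr genes in 18 of 19. Over 8 families the lowest adjusted p in Fisher's exact test was 0.051, whereas with Pax, T-box, Sox and Fox genes counted with the homeobox genes, as first defined, 6 of the 8 passed. Those developmental genes were positive in 19 of 39 cases (Fisher's exact test, adjusted p = 0.0128), but homeobox genes alone in 7 of 11 (adjusted p = 0.502). With families narrowed towards subunit genes, proteasome genes were positive in 18 of 18 cases and RNA polymerase genes in 18 of 18 (Fisher's exact test, adjusted p = 0.0234 for both). Mitochondrial ribosomal protein genes were positive in 23 of 25 (Fisher's exact test, adjusted p = 0.0786) and NADH dehydrogenase genes in 16 of 17 (adjusted p = 0.0878). Beside assembly factors and chaperones, this left out Psme4 (effect -1.16 in the authors' deposited table) and Polr2m (-0.674). They were the only negative regions of the Psma to Psmg and Polr families, so the counts of 18 of 18 follow from leaving them out. F-box genes were positive in 23 of 36 cases and lysine demethylase and methyltransferase genes in 16 of 25, with no call under any definition used. With GC categories and width in a logistic model (n = 6950 regions) the histone genes had an odds ratio of 0.358 (0.123 to 1.04, p = 0.0597), opposite in direction to that without covariates (3.07).

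A hypothesis was that the STAT consensus goes with positive effects in distal regions and not in promoters. The ratio of its distal to its promoter odds ratio was 1.55 (n = 14973 regions, 1.08 to 2.23, p = 0.0182), with an adjusted p of 0.321 over the consensus sequences tested in this way. The difference thus did not pass the correction, and whether the relation differs stays open.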
